A study of Mus musculus with 32 samples.

How the data were processed

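ATAC-seq marks open chromatin by the places where a transposase inserts sequencing adapters. It was applied here to mouse embryonic fibroblasts and to cells derived from them during reprogramming with Oct4, Sox2, Klf4 and c-Myc (OSKM). The 32 samples fell into 15 groups by their titles, source names and descriptions. Each description names 1 peak file, and all samples of a group name the same file, so each group has 1 deposited list of peaks. The Thy1+ groups hold 3 samples each, from days 3, 6 and 9, and the SSEA1-Thy1- and SSEA1+ groups hold 2 samples each, from days 6 and 9. All other groups hold 2 samples of 1 day.

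Per the submitters' processing notes, FastQC, Trim Galore, cutadapt, Bowtie2, SAMtools, Picard and MACS2 were used, with the builds mm10 and GRCm38. Their versions, roles, filters, peak threshold, any shift of reads for the transposase's binding, and how the samples of a group were combined are not given in the sources used here. The deposited lists hold intervals of 400 bp on the chromosomes 1 to 19, X and Y. Their score column is 0 throughout, so no height, fold or p-value per peak was used, and peaks could not be ranked or filtered. No count of reads was used, so the sequencing depth behind each list is unknown. A list from deeper libraries, or from 3 samples in place of 2, can hold more peaks with no change in the cells.

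Peak positions were shared in 3 sets of lists. Within the set of day 0 and sorted lists, within the day 10 set and within the day 12 set, 44.0% to 95.6% of the positions of the shorter list were identical between lists. Between sets 0.664% to 0.887% were. Comparisons between lists therefore stay within a set wherever possible, and a share that crosses sets is compared only with shares that cross the same sets.

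Overlapping intervals within a list were merged, and a peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Lost peaks lie only in the control list and gained peaks only in the treated list. There were 8 pairs: CTCF shRNA against control shRNA at day 0 and in the Thy1+, SSEA1-Thy1-, SSEA1+ and GFP+ cells, CTCF overexpression against its control at day 10, CTCF overexpression with Smarca5 shRNA against CTCF overexpression alone, and Smarca5 shRNA against control shRNA at day 12. Closing sites were peaks of the day 0 control list outside the GFP+ control list, opening sites the reverse, and stable sites the day 0 peaks in both. With 1 list per group there is no replicate check, and no p-value was computed within a pair. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. An exact two-sided sign-flip permutation test was run over the 5 CTCF shRNA pairs, where the smallest possible p is 0.0625, and over the 3 pairs of Thy1+, SSEA1-Thy1- and SSEA1+ cells, where it is 0.25. Benjamini-Hochberg adjustment covered 17 and 2 measures, respectively.

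The gene table is of the assembly GRCm38.p6, the build named in the labels, and 21883 protein-coding genes with 1 position were used. In the day 0 control list 66.1% of them had a peak within 1 kb of a gene end, against 26.7% when the genes were moved by 20 kb. The table gives no strand. The planned promoter was therefore replaced by either end of the gene with 1 kb on either side, called a gene-end peak, and the planned distance from the transcription start by the gene body with 50 kb on either side. A gene-end peak can thus lie at the 3' end of a gene. A number given from the share of all genes applies the rate of all 21883 genes to the list genes with, or without, a gene-end peak in the control. It is not matched on peak number or type of gene, so an excess over it does not measure enrichment. For 15 gene lists the relative log2 is the log2 ratio of the distinct peaks near the list's genes, treated over control, minus the same ratio of whole lists. It was placed among 10000 random gene lists of the same size, matched on control peak number in 10 bins. This is a description of these lists and not a test of the condition. Random lists are scattered over the genome, so for the Hox and clustered protocadherin lists, whose genes are neighbours, their range is too narrow. The protocadherin locus was therefore also compared with 10000 random regions of its length whose control peak number lay within 20% of its own. The lists were pluripotency, fibroblast, epithelial, AP-1 and partners, chromatin architecture, Hox, clustered protocadherins, cell cycle arrest, housekeeping, and markers of haematopoietic, endothelial, neural, keratinocyte and endoderm or trophoblast cells, plus the 3 genes behind the sort gates. The protocadherin list was set by symbol prefix. A fault in the code had first left out part of its genes, and was corrected after the first values were seen.

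The gene lists and the rule for named genes were fixed before the data were examined. Per pair they are the list genes with a gene-end peak in exactly 1 of the 2 lists, at most 25 in the order of the lists, with Hox and protocadherin genes as counts only, plus Ctcf, Smarca5, Pou5f1, Nanog, Thy1, Fut4 and Cdh1 in every list by the peaks within the gene and 10 kb on either side. The planned 3 highest lost and gained peaks per pair were left out, as there is no value per peak. The CTCF motif analysis was left out, as no genome sequence was used here. Alternatives covered the overlap rule, the sex chromosomes, each pair left out, the distances to genes, identical positions, sites supported by other lists, and another definition of closing and opening sites.

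Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data. On the SSEA1+ control list of 135749 peaks it recovered 200 of 200 simulated losses and 300 of 300 simulated gains. On that list thinned at random, 14 of 200 random gene lists over 21883 genes lay outside the central 95%.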

Results

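Open chromatin was mapped by ATAC-seq in 32 samples of mouse fibroblasts on their way to induced pluripotent stem cells. CTCF, the zinc finger protein that marks domain borders and insulators, was knocked down by shRNA or overexpressed, and Smarca5, the ATPase of ISWI chromatin remodelling complexes, was knocked down. The sorted cells form the usual order of reprogramming: Thy1+ cells that keep the fibroblast surface marker, SSEA1-Thy1- cells that have left it, SSEA1+ cells that have gained an early stem cell marker, and GFP+ cells, in which a reporter of Pou5f1 is on. The 15 groups were each represented by 1 deposited peak list, from 43618 peaks after merging in the unsorted day 12 control to 213386 in Thy1+ cells with CTCF shRNA. Read depth is unknown, and no value below has a replicate check. Intervals are exact Clopper-Pearson 95% intervals and cover counting error over peaks only.

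The first comparison followed the control cells from day 0 to the GFP+ state. Fibroblast genes lost most of their surrounding peaks on the way, and pluripotency and epithelial genes held more. The 35 fibroblast genes, such as those for collagens and mesenchymal transcription factors, had 672 peaks in or within 50 kb of them at day 0, 785 in Thy1+, 568 in SSEA1-Thy1-, 409 in SSEA1+ and 255 in GFP+ cells. The 30 pluripotency genes had 263 peaks at day 0 and 399 in GFP+ cells, and the 20 epithelial genes 240 and 313. Prrx1, a mesenchymal homeobox factor at chromosome 1, 163245119 to 163315145 (GRCm38), had 17 peaks within 10 kb at day 0 and 3 in GFP+ cells, whereas Esrrb, an orphan nuclear receptor of the pluripotency network at chromosome 12, 86361117 to 86521628, had 8 and 19.

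Whole lists shortened from 153962 peaks at day 0 to 91337 in GFP+ cells, so the gene lists were set against that. The relative log2 from day 0 to GFP+ cells was -0.64 for the fibroblast list (random lists -0.08 to 0.43), 1.35 for the pluripotency list (0.23 to 0.77) and 1.14 for the epithelial list (0.21 to 0.71). The Hox list also stood above its random range, at 0.66 against an upper bound of 0.31, as did the clustered protocadherins, at 1.35 against 0.39, though random lists are scattered and these genes are not. Haematopoietic, endothelial and neural markers lay inside theirs, at 0.80, 0.43 and 0.31. Gene-end peaks were present at 16 of 30 pluripotency genes at day 0 and at 26 in GFP+ cells, and at 33 and 27 of 35 fibroblast genes. Nanog, a core pluripotency factor, had a gene-end peak in SSEA1+ and GFP+ control cells and in none of the day 0, Thy1+ or SSEA1-Thy1- control lists. Cdh1, which encodes E-cadherin, had 8 peaks within 10 kb at day 0 and 16 in GFP+ cells, and Thy1 had 4 and 2. Other genes fixed beforehand moved little: Pou5f1 had 7 and 7, Fut4 2 and 2, and Ctcf and Smarca5 each 4 and 3. Pou5f1, the gene of the reporter, had a gene-end peak at day 0 and in SSEA1-Thy1- and GFP+ control cells. It had none in the Thy1+ and SSEA1+ control lists.

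In all, 104146 sites closed between the day 0 and GFP+ control lists (67.6% of the day 0 peaks), 41521 opened (45.5% of the GFP+ peaks) and 49816 were stable. Thy1+ control cells still held 79.5% of the closing sites (79.2% to 79.7%), SSEA1-Thy1- cells 28.9% (28.6% to 29.2%) and SSEA1+ cells 15.1% (14.9% to 15.4%). The share of opening sites held differed less between these populations, with 49.6% in Thy1+, 58.7% in SSEA1-Thy1- and 64.1% in SSEA1+ control cells. The Thy1+ control list, from 3 samples, is the longest control list (194446 peaks), which can raise its shares.

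**Figure D1:**
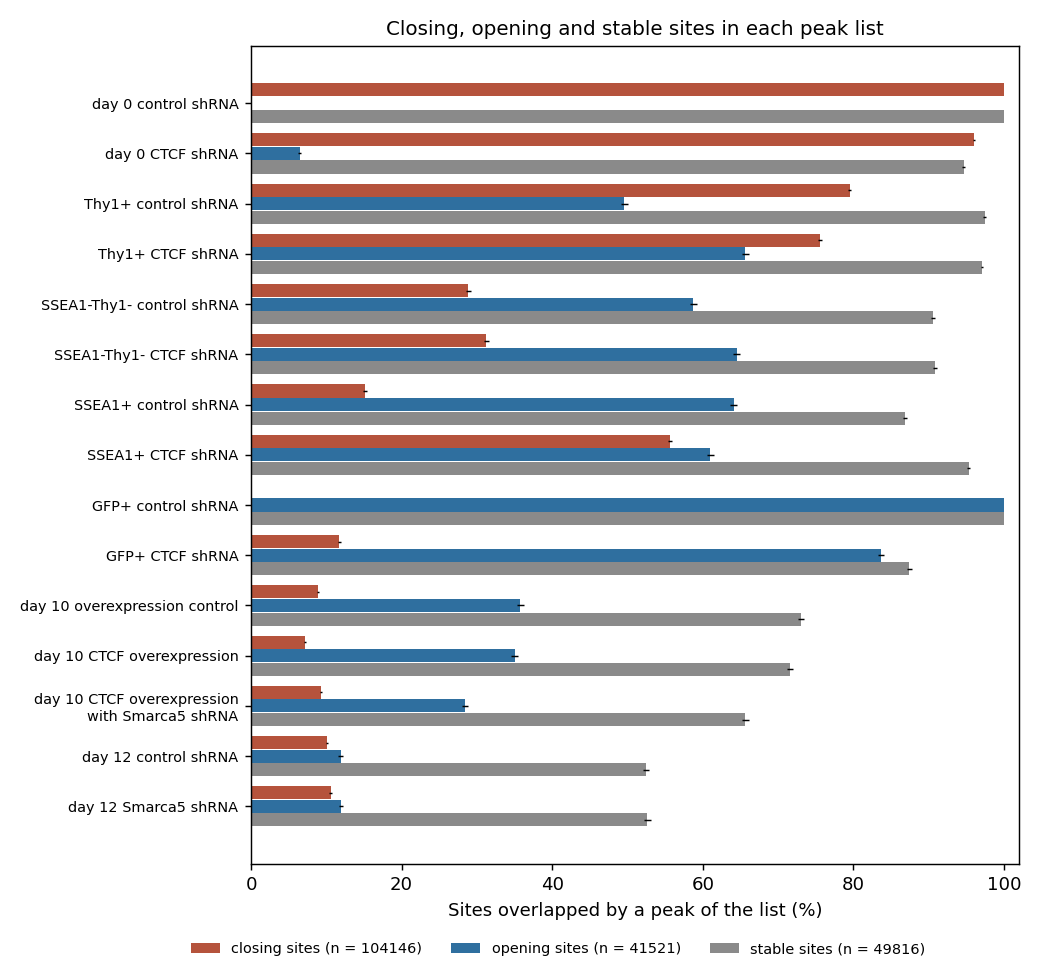
Share of closing, opening and stable sites (percent, horizontal axis) overlapped by a peak in each of the 15 lists (vertical axis), with exact 95% intervals. The SSEA1+ list with CTCF shRNA holds 55.6% of the closing sites, against 15.1% in its control, while the day 0 and GFP+ control lists stand at 0% or 100% because they define the sites.

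The second comparison asked what CTCF knockdown did to accessibility in each population. With CTCF shRNA, more peaks were gained than lost in all 5 pairs, least at day 0 and most in SSEA1+ cells. At day 0, 6853 peaks were lost and 7503 gained, in Thy1+ cells 15947 and 34887, in SSEA1-Thy1- cells 13215 and 25832, in SSEA1+ cells 10849 and 58741, and in GFP+ cells 13029 and 25158. Lost and gained peaks lay mostly away from gene ends: in GFP+ cells 5.43% of lost and 3.76% of gained peaks were within 1 kb of the end of a gene, against 19.5% of shared peaks. The mean log2 ratio of peak number was 0.17 ± 0.16 (SD, n = 5 pairs), with 5 of 5 pairs above 0, from 0.01 at day 0 to 0.44 in SSEA1+ cells. The exact two-sided sign-flip test gave p = 0.0625, the smallest that 5 pairs allow, and 0.354 after Benjamini-Hochberg adjustment over 17 measures, and without the SSEA1+ pair the mean was 0.11.

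**Figure D2:**
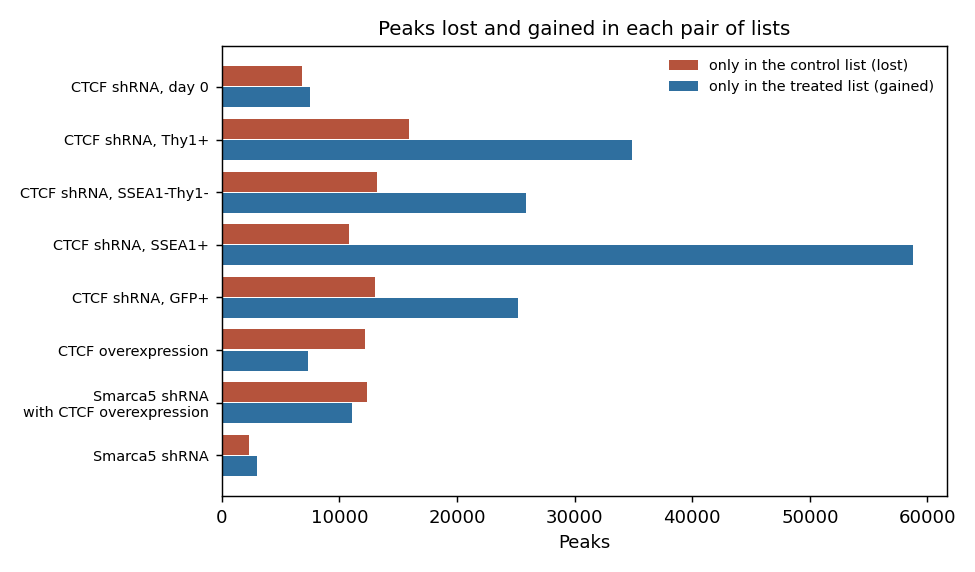
Number of peaks only in the control list (lost) and only in the treated list (gained) on the horizontal axis, for each of the 8 pairs of lists on the vertical axis. Gained peaks exceed lost peaks in each CTCF shRNA pair, most in SSEA1+ cells (58741 against 10849), and fall short of them with CTCF overexpression (7352 against 12205).

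The targeted gene itself kept a gene-end peak in all 15 lists. Ctcf had 4 peaks within 10 kb in the day 0 control and 5 with CTCF shRNA, 5 and 6 in Thy1+ cells, 4 and 4 in SSEA1-Thy1- and in SSEA1+ cells, and 3 and 2 in GFP+ cells. An shRNA acts on the transcript, so these peaks do not measure the knockdown.

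The SSEA1+ list with CTCF shRNA held more peaks near fibroblast genes than its control. Whether this came from Thy1+ cells in the sort, an exchange of samples or delayed closing stays open, as set out below. The fibroblast list had 409 peaks in the control and 692 with CTCF shRNA, a relative log2 of 0.32 that lay above all 10000 random lists (central 95% -0.19 to 0.02). Prrx1 had 7 peaks within 10 kb in the control and 19 with CTCF shRNA, close to its 17 at day 0. Runx1, of the list of AP-1 and partners, had 20 and 31. That list as a whole stood at 0.00, near the top of its random range (-0.26 to 0.02), and above the range at 100 kb (percentile 98.95). Pluripotency genes had 350 and 403 peaks, which given the longer list is a relative log2 of -0.23 (random lists -0.22 to -0.01), and epithelial genes 322 and 364, at -0.26 (-0.25 to -0.00). Nanog had 6 peaks within 10 kb in the control and 4 with CTCF shRNA.

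Of the closing sites, 55.6% (55.3% to 55.9%) were held in SSEA1+ cells with CTCF shRNA, 40.5 percentage points above the control. Opening sites were held at 61.0% against 64.1%, and stable sites at 95.3% against 86.9%. Among the 58741 gained peaks, 81.6% (81.3% to 81.9%) were already open at day 0, and among the 10849 lost peaks 14.4% were (13.8% to 15.1%). The other populations did not share this: 19.1% of gained and 68.1% of lost peaks were open at day 0 in Thy1+, 44.3% and 66.8% in SSEA1-Thy1-, and 48.6% and 48.0% in GFP+ cells. Of shared peaks, 46.0% were open at day 0 in SSEA1+, 67.5% in Thy1+, 48.1% in SSEA1-Thy1- and 55.6% in GFP+ cells. In Thy1+ cells lost and shared peaks were thus alike in this. The Thy1+ control already held 79.5% of closing sites, so fewer day 0 sites were left to gain there. Gene-end peaks were gained at 3 of the 5 fibroblast genes that had none in the control (Col6a1, Postn and Prrx1), against 0.458 from the share of all genes, and at Runx1, Rab25, Csf1r, Itgam, Neurog2 and Gata4. They were lost at Nanog, Crb3, Wapl, Actb and Tfap2c. The fibroblast value held at 20 kb and 100 kb, but the pluripotency value came inside the random range at 100 kb and on autosomes, the epithelial value at 20 kb and 100 kb, and within 2.5 kb of gene ends 1 of these 14 genes, Gata4, still differed.

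Thy1, which encodes the surface marker of the fibroblast gate, had 2 peaks within 10 kb in the SSEA1+ control, 4 with CTCF shRNA and 4 in the Thy1+ control. Of the other cell type markers in SSEA1+ cells, the keratinocyte list was at 0.08, the endoderm and trophoblast list at 0.02, the haematopoietic list at -0.08 and the neural list at -0.17, each inside its random range, but at 100 kb the endoderm and trophoblast list stood at 0.10 and above it.

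**Figure D3:**
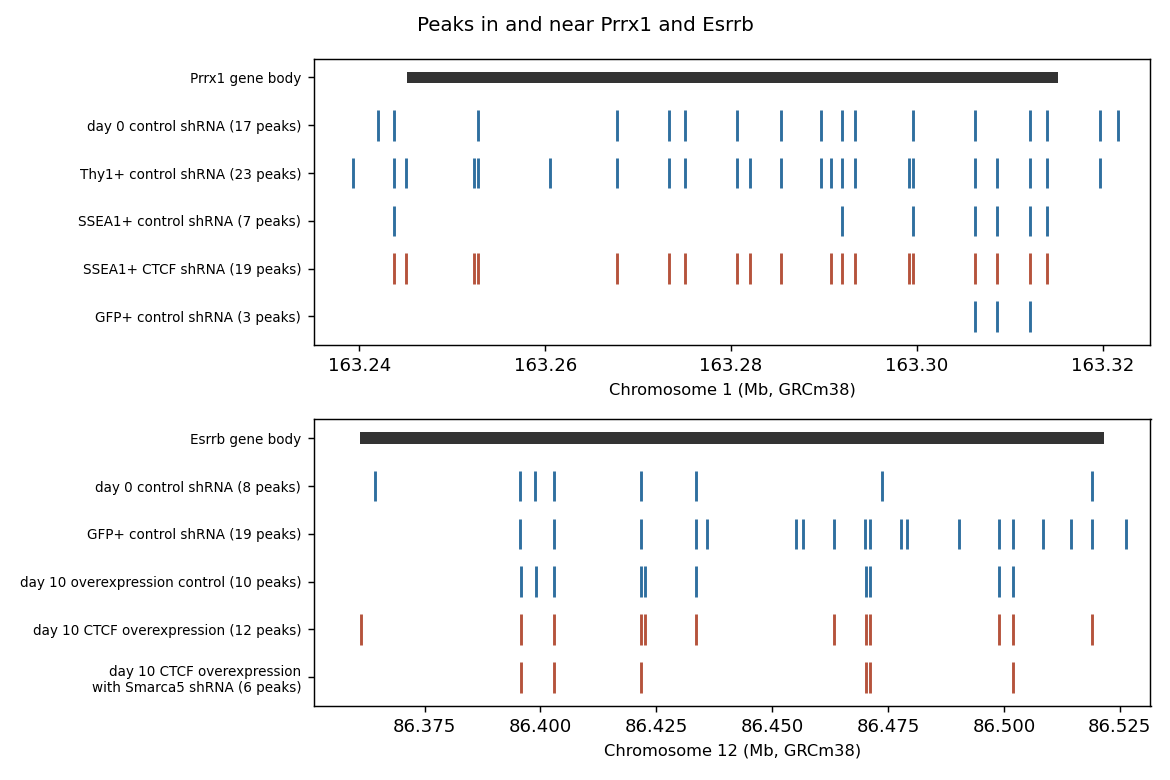
Peaks (vertical ticks at peak centres) along chromosome 1 near Prrx1 and chromosome 12 near Esrrb (Mb, GRCm38), with the gene body as a black bar, in 5 lists each, control lists in blue and treated lists in red. Near Prrx1 the SSEA1+ list with CTCF shRNA has 19 peaks and its control 7, and near Esrrb the day 10 lists have 10, 12 and 6 peaks.

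The Thy1+ lists differed in the other direction, and an exchange of samples stays open here too. With CTCF shRNA the list held fewer closing sites, 75.6% (75.3% to 75.9%) against 79.5%, and more opening sites, 65.6% (65.2% to 66.1%) against 49.6%. Pluripotency genes had 384 peaks in the control and 450 with CTCF shRNA, a relative log2 of 0.09 (random lists -0.08 to 0.05), and 5 of the 13 pluripotency genes without a gene-end peak gained one, against 0.884 from the share of all genes. These were Prdm14, Dppa2, Dppa5a, Lin28a, an RNA-binding repressor of let-7 microRNAs, and Tdgf1. Neural markers had 228 and 284 peaks, a relative log2 of 0.18 (-0.12 to 0.08), the only list of another cell type outside its range there. Such gains were not limited to pluripotency genes. Of genes without a gene-end peak, 2 of 4 neural (Dcx and Sox1), 2 of 5 keratinocyte (Krt6a and Trp63) and 2 of 6 endothelial genes (Sox17 and Eng) gained one. None was gained at the 3 epithelial, 5 haematopoietic and 3 endoderm or trophoblast genes without one. Wapl, Neurog2 and Elf5 lost theirs. At 100 kb the pluripotency value was 0.04 and inside the random range, and within 2.5 kb of gene ends 2 of the 5 pluripotency genes, Dppa2 and Dppa5a, still differed.

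SSEA1-Thy1- cells showed smaller shifts in closing and opening sites than Thy1+ cells, though the lists differed as much, with 77.9% against 77.8% of sites in both. Opening sites were held at 64.5% (64.1% to 65.0%) against 58.7%, and closing sites at 31.3% (31.0% to 31.5%) against 28.9%. The fibroblast list, with 568 and 574 peaks, stood at a relative log2 of -0.10, just below its random range at percentile 2.16 and inside it at 20 kb, and the pluripotency list stood at 0.01, inside its range. Gene-end peaks were gained at Lin28a, Tdgf1, Fap, Actb, Cdh5 and Pax6 and lost at Col6a1 and Csf1r, of which Pax6 alone still differed within 2.5 kb. Over the 3 intermediate populations the mean change was 13.0 percentage points for closing sites (SD 24.0, 2 of 3 pairs above 0, exact two-sided p = 0.75) and 6.24 for opening sites (SD 9.57, 2 of 3 pairs above 0, exact p = 0.5). Both adjusted p were 0.75 over 2 measures, and the smallest possible exact p is 0.25.

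GFP+ cells with CTCF shRNA had more peaks overall but no more of them at pluripotency genes. The pluripotency list had 399 peaks in both lists, a relative log2 of -0.18 (random lists -0.16 to 0.00), which at 100 kb was -0.13 and inside the range. The fibroblast list had 255 and 301 peaks, a relative log2 of 0.06 inside its range (-0.14 to 0.06) but above it at 20 kb, at 0.12, and at 100 kb. Moreover 4 of the 8 fibroblast genes without a gene-end peak gained one, against 0.383 from the share of all genes. These were the collagen genes Col3a1 and Col6a3, Acta2, which encodes smooth muscle actin, and S100a4; Col3a1 and Col6a3 still differed within 2.5 kb. Ywhaz also gained a gene-end peak, and Vwf and Elf5 lost theirs. The list held 83.7% of the opening and 11.7% of the closing sites, but its own control defines both classes.

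At day 0 the lists were close to each other, with 91.1% of sites in both. The pluripotency list stood at 0.03 and the fibroblast list at 0.01, inside their random ranges. Gene-end peaks were lost at Zfp42, Klf4, Prdm14, Cldn3, Pkp3, Neurod1 and Cdx2 and gained at Tdgf1, Tdh, Cdkn1a, Actb, Sox1 and Ascl2. Even here 3 of 16 pluripotency genes lost theirs, against 0.206 from the share of all genes, so an excess of this kind was not limited to pairs with many differences. Nor was it limited to this list: 2 of 15 epithelial genes lost theirs, against 0.193. Fibroblast genes lost 0, against 0.425. Of these 13 genes Zfp42, Tdh and Cdkn1a still differed within 2.5 kb.

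Among the remaining lists, the clustered protocadherins, neuronal adhesion genes whose promoter choice depends on CTCF, held relatively fewer peaks with CTCF shRNA in 5 of 5 pairs. The mean relative log2 over the 57 genes was -0.20 (SD 0.10; exact two-sided p = 0.0625, adjusted p = 0.354 over 17 measures). That test is against 0, but matched random lists were themselves mostly below 0. They ranged from -0.17 to 0.00 in SSEA1+ and from -0.14 to -0.03 in GFP+ cells. A count of 5 of 5 is thus partly built into the measure. The locus, at chromosome 18 from 36930285 to 37841873, had 57 peaks in the day 0 control and 56 with CTCF shRNA, 67 and 63 in Thy1+, 54 and 51 in SSEA1-Thy1-, 53 and 57 in SSEA1+ and 92 and 86 in GFP+ cells. Against random regions of its length the relative log2 lay below the central 95% in GFP+ cells (-0.28, bound -0.23) and just below it in Thy1+ (-0.22, bound -0.22) and SSEA1-Thy1- cells (-0.20, bound -0.20), and inside it at day 0 (-0.03) and in SSEA1+ cells (-0.33, bound -0.35).

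For the other lists the mean relative log2 over the 5 pairs was -0.06 for pluripotency, 0.04 for fibroblast, -0.09 for epithelial, -0.05 for AP-1 and partners, -0.04 for chromatin architecture, -0.09 for Hox, -0.07 for cell cycle arrest and -0.11 for housekeeping genes. It was -0.05 for haematopoietic, -0.01 for endothelial, -0.02 for neural, -0.03 for keratinocyte and -0.04 for endoderm and trophoblast markers, and -0.01 for the genes behind the sort gates. Their exact p was 0.125 or above, with adjusted p of 0.354 or above over the same 17 measures. Those tests are also against 0, while the ranges of random lists were centred below 0 in the sorted populations. Besides the pluripotency, fibroblast, epithelial and neural values given above, the Hox list lay outside its random range at day 0, at 0.06, and in SSEA1+ cells, at -0.29, the latter inside at 100 kb. Over all 8 pairs, 9 of 104 values of the lists other than Hox and clustered protocadherins lay outside the central 95% of random lists, where the nominal number is 5.2. In the simulation without an effect, 14 of 200 random gene lists lay outside. The 104 values are not independent, as the same genes recur in each pair and some pairs share a peak list.

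**Figure D4:**
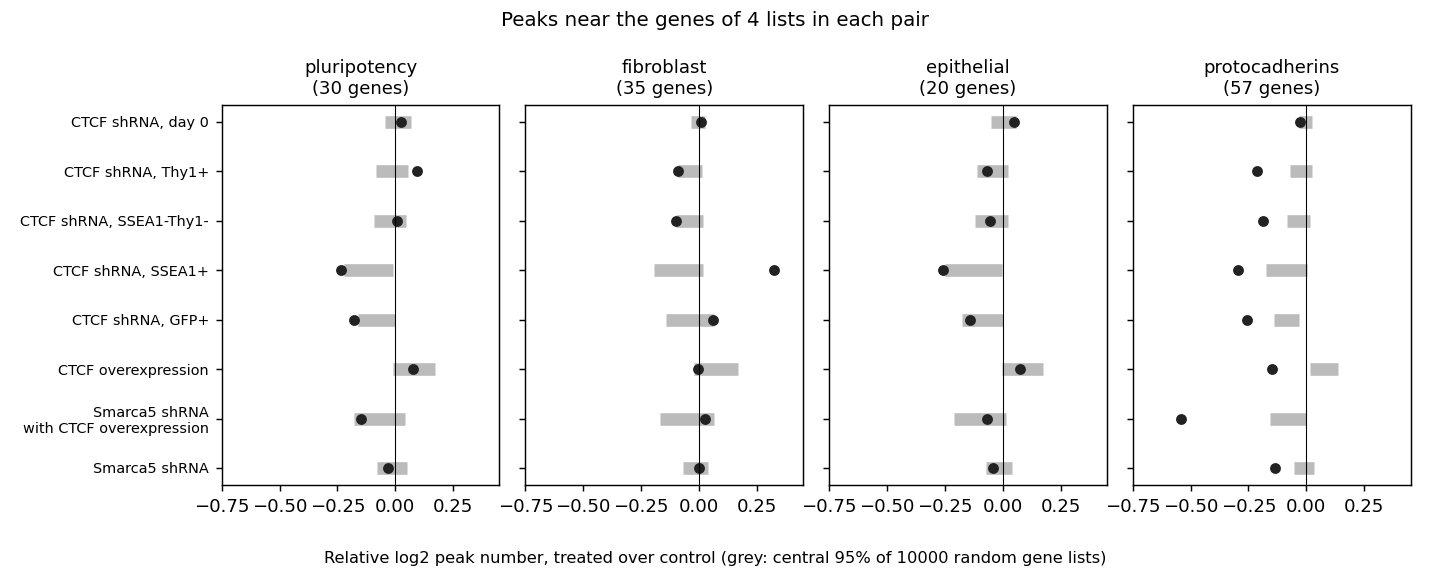
Relative log2 peak number (treated over control, after the ratio of whole lists; horizontal axis) near the genes of 4 lists in each of the 8 pairs (vertical axis), as black points, with the central 95% of 10000 random gene lists in grey. The fibroblast list stands at 0.32 in SSEA1+ cells with CTCF shRNA, and the protocadherin list at -0.54 with Smarca5 shRNA and CTCF overexpression; the grey ranges are too narrow for protocadherins, which lie in 1 locus.

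Few sites were lost again and again with CTCF shRNA. Of 266864 sites in the 10 lists, 501 were lost in 3 of the 5 pairs and 43 in 4, against 209 and 4.62 from independent lists, and 3068 were gained in 3 pairs, against 2574. Thy1+ and SSEA1+ cells shared 3485 gained sites, against 7656 from independent lists, while 4375 sites gained in Thy1+ cells were lost in SSEA1+ cells, against 1413. SSEA1-Thy1- and SSEA1+ cells shared 10020 gained sites, against 5665, but opposite changes were also in excess: 6397 sites lost in SSEA1-Thy1- cells were gained in SSEA1+ cells, against 2897, and 2696 gained in SSEA1-Thy1- cells were lost in SSEA1+ cells, against 1046. The independent values take no account of which sites each population can gain or lose.

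The third comparison was CTCF overexpression at day 10 of OSKM reprogramming. The list was shorter than its control, with 12205 peaks lost and 7352 gained, and it held fewer closing sites, 7.13% (6.97% to 7.29%) against 8.91% (8.74% to 9.08%), and fewer stable sites, 71.6% (71.2% to 72.0%) against 73.1% (72.7% to 73.5%). Pluripotency genes had 249 peaks in the control and 245 with CTCF overexpression, and 3 of the 8 pluripotency genes without a gene-end peak gained one: Pou5f1, Esrrb and Gdf3, against 0.294 from the share of all genes. Esrrb and Gdf3 had none in the GFP+ control list, however, and Pou5f1 already had one in the day 0 control list. These gains alone therefore do not show a move towards the GFP+ state. Prdm14 lost its gene-end peak. Prrx1 went from 7 peaks within 10 kb to 4 and lost its gene-end peak, and Pdgfra, a growth factor receptor of fibroblasts, gained one. Ctcf had 2 peaks within 10 kb in the control and 4 with overexpression; reads from an introduced CTCF or OSKM sequence would fall on the same genes and were not separated here.

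The relative log2 was 0.08 for the pluripotency list, -0.01 for the fibroblast list and 0.08 for the epithelial list, each inside its random range, though at 100 kb the fibroblast value of -0.02 lay below it. The keratinocyte list stood at -0.09, inside its range, and at -0.23 and below it with 20 kb. The Hox list stood at 0.00, below its range (0.03 to 0.14), and inside it with 20 kb. Opening sites were held at 35.0% (34.6% to 35.5%) against 35.8% (35.3% to 36.2%). Gene-end peaks were also lost at Krt19, Cldn6, Sox17, Vwf, Neurog2 and Hand1 and gained at Jund. Within 2.5 kb of gene ends, Esrrb, Prrx1, Krt19 and Vwf were the 4 of these 13 genes that still differed.

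The next comparison added Smarca5 shRNA to CTCF overexpression at day 10. Pluripotency genes had fewer accessible sites with it. Gene-end peaks were lost at 6 of the 24 pluripotency genes that had one (Pou5f1, Nanog, Sox2, Esrrb, Dppa5a and Nr0b1), against 1.10 from the unmatched share of all genes, and none was gained. Esrrb had 10 peaks within 10 kb in the control, 12 with CTCF overexpression and 6 with Smarca5 shRNA added, and the pluripotency list had 249, 245 and 217 peaks. Of all 13939 genes with a gene-end peak, 638 lost it (4.58%), while 161 genes gained one. Within 2.5 kb of gene ends, Esrrb was the 1 pluripotency gene of the 6 that still differed, and the list's relative log2 of -0.15 lay inside the random range (-0.18 to 0.04). Esrrb was also the only gene of the 6 with no gene-end peak in the GFP+ control list.

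Opening sites were held at 28.4% (28.0% to 28.9%) with Smarca5 shRNA, against 35.0% with CTCF overexpression alone and 35.8% in the control. Stable sites were held at 65.7% against 71.6%, and closing sites at 9.28% (9.11% to 9.46%) against 7.13%. Prrx1 went from 4 peaks within 10 kb to 7 and regained its gene-end peak, and Vwf, Neurog2 and Dsg3 gained one. Pdgfra, Crb3, Jund, Smarca1, the other ISWI ATPase, Eng and Dcx lost theirs. Of these 10 genes Crb3, Jund, Eng and Neurog2 no longer differed within 2.5 kb. The keratinocyte list, with 64 and 71 peaks, stood at 0.18 (-0.29 to 0.16), inside its range at 100 kb, and the protocadherin locus had 36 and 23 peaks, a relative log2 of -0.62 below the central 95% of random regions (-0.47 to 0.35). Smarca5 had 3 peaks within 10 kb with CTCF overexpression and 2 with its shRNA.

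Across the 3 day 10 lists, 52489 of 83944 sites were in all of them. The list with Smarca5 shRNA held 36.8% (35.7% to 37.96%) of the 7352 peaks found only with CTCF overexpression and 56.9% (56.0% to 57.8%) of the 12205 found only in the control. Exchanging the 3 lists at random at each site gave 55.3% over 100 draws (54.2% to 56.4%). Both comparisons at day 10 share the CTCF overexpression list, so a site called there by chance, Pou5f1 and Esrrb included, counts as gained in the former and as lost in the latter.

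The last comparison was Smarca5 shRNA without CTCF overexpression, in unsorted cells at day 12. The lists differed little, with 88.5% of sites in both, 2355 peaks lost and 3016 gained. Dppa5a, a germ and stem cell gene, and Tdh, which encodes the threonine dehydrogenase of mouse stem cells, lost their gene-end peaks, 2 of 20 pluripotency genes against 0.229 from the share of all genes, and no pluripotency gene gained one. Krt19, Sox18 and Cdx2 lost theirs and Col6a3 gained one; all but Cdx2 still differed within 2.5 kb. The pluripotency list had 147 peaks in the control and 146 with Smarca5 shRNA, the fibroblast list 210 and 213, and both stood inside their random ranges at -0.03 and -0.00.

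Opening sites were held at 11.9% (11.6% to 12.2%) in the control and at 11.9% (11.6% to 12.3%) with Smarca5 shRNA, and closing sites at 10.1% and 10.6%. Housekeeping genes, with 121 and 115 peaks, stood at -0.10 (-0.09 to 0.05), and with 20 kb or on autosomes they were inside the random range. The protocadherin locus had 19 and 17 peaks, inside the range of random regions. Smarca5 had 2 peaks within 10 kb in the control and 1 with its shRNA, and Fut4, whose enzyme makes the SSEA1 epitope, had 1 in each.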

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

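The tests of deeper calling, of sites staying open, of the Smarca5 list and of CTCF dosage were chosen after their results were seen, and the tests of Thy1+ cells, of exchanged samples and of local variation before theirs.

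With CTCF shRNA, Thy1+, SSEA1-Thy1- and SSEA1+ cells did not move the same way, and these differences between populations were not tested, as each has 1 list. The share of closing sites held differed from control by -3.90 percentage points in Thy1+, 2.39 in SSEA1-Thy1- and 40.5 in SSEA1+ cells, and the share of opening sites by 16.0, 5.80 and -3.11 points. The pluripotency list stood at a relative log2 of 0.095 in Thy1+ but -0.23 in SSEA1+ and -0.18 in GFP+ cells. The fibroblast list stood at -0.10 in SSEA1-Thy1- and 0.32 in SSEA1+ cells. The Hox list stood at 0.065 at day 0 and -0.29 in SSEA1+ cells.

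For the closing sites in SSEA1+ cells, deeper calling of the CTCF shRNA list is argued against as the whole cause, since the share of opening sites held differed by -3.11 percentage points. Thy1+ cells among the sorted SSEA1+ cells may have contributed: outside the SSEA1+ control list, 48.9% of sites open in Thy1+ and not in day 0 control cells were gained, against 7.93% of those open at day 0 and not in Thy1+ cells. Delayed closing after the Thy1+ state would leave the same contrast, so these shares cannot tell it from Thy1+ cells in the sort. An exchange of a Thy1+ and an SSEA1+ sample with CTCF shRNA stays open too: of sites outside the Thy1+ control list, 58.0% of those open in SSEA1+ and not in SSEA1-Thy1- control cells were gained in Thy1+ cells, against 54.6% of the reverse, a small gap. Whether fibroblast sites stay open under CTCF shRNA beyond the Thy1+ state was not decided by SSEA1-Thy1- cells, where closing sites were 2.39 points higher but opening sites 5.80 points in a longer list, the fibroblast list stood at -0.10, and 66.8% of lost against 44.3% of gained peaks were open at day 0. Of the shared peaks of SSEA1-Thy1- cells, 48.1% were. Purity of the sort, an exchange and delayed closing all stay open.

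The list with Smarca5 shRNA and CTCF overexpression at day 10 held fewer opening sites. Shallower calling is argued against as the whole cause, because the share of closing sites held was 2.15 percentage points higher. Whether there were fewer cells near the GFP+ state stays open: 69.6% of lost and 26.2% of gained sites were in the GFP+ control list, but that list defines the opening and stable sites, so this restates the pattern. The stable sites, whose share differed by -5.94 percentage points, do not decide it either, since the GFP+ control list holds all of them by definition and any other list can only hold fewer. A direct effect of Smarca5 shRNA on stable sites, and a difference in data quality, stay open and were not tested.

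The protocadherin locus held relatively fewer peaks with CTCF shRNA. Local variation of any region of this length was argued against only narrowly by the bound set beforehand. Of the 5 pairs, 3 lay below the central 95% of random regions, with 2 of these 3 close to the bound (percentiles 2.2 in Thy1+ and 2.4 in SSEA1-Thy1- cells). The random regions were matched on length and control peak number but not on gene ends, and gained peaks lay mostly away from gene ends. The comparison thus cannot tell a change particular to this locus from its many gene ends. Whether its peak number follows the level of CTCF stays open, as the relative log2 with CTCF overexpression was -0.22, inside the range of random regions (-0.27 to 0.31). The locus was relatively lower in all 8 pairs, both Smarca5 pairs included, so the pattern is not particular to CTCF shRNA. The bound was set before the first values, but the gene list was completed after them, when a fault in the code was corrected.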

How the results depend on the processing

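Identical positions, supported sites, the other definition of sites and the sex chromosome setting for shares and gene lists were chosen after seeing the data. An overlap of 50%, autosomes only, identical positions and supported sites left each of the 16 counts of lost and gained peaks within 1.5 times, and all but identical positions, which were not run there, the 3 course counts. The overlap rule and identical positions could change these counts little, as most positions were identical within a pair. Supported sites lowered the peaks gained with CTCF overexpression from 7352 to 5321. The overlap of 50% and autosomes moved none of the 12 differences in closing and opening sites, or the 2 day 10 shares, beyond their intervals. With sites called alike in both shRNA lists, 4 of 12 differences moved in size and kept their direction: closing 41.2 and opening -3.84 percentage points in SSEA1+ cells, opening 17.0 in Thy1+ cells, and opening -7.81 with Smarca5 shRNA and CTCF overexpression; the cause was not tested. Leaving out each pair gave a mean log2 peak number of 0.11 to 0.22, lowest without the SSEA1+ pair, with exact p = 0.125 throughout. With 20 kb, the fibroblast list in GFP+ cells stood at 0.12, and the pluripotency list at -0.29 in SSEA1+ and 0.044 in SSEA1-Thy1- cells. With 100 kb, the pluripotency list stood at -0.13 in GFP+, 0.041 in Thy1+ and -0.0092 in day 0 cells; the cause was not tested. For the other lists, 22 of 104 values moved with 20 kb and 15 of 104 with 100 kb. Calls for single genes depended most on the setting: 31 of 92 gene-end differences remained within 2.5 kb. Lists of equal length and a stricter threshold were not run, as the lists used hold no value per peak, and the motif settings were not run without a genome sequence. No paired analysis was possible because each group has 1 list, with no value to pair by replicate number; the sign-flip tests pair whole lists of treated and control cells instead. Depth is unknown, so differences in list length cannot be separated from depth.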

Other observations

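The genes in this part were chosen after their values were seen, by the difference in peaks within 10 kb beyond the ratio of the whole lists, and no explanation was tested. In SSEA1+ cells with CTCF shRNA, the genes first by this difference, scaled by peak number, were Adamts12, Glis3, Ror1, Prkg1 and Gas7. Adamts12, a secreted metalloprotease, had 7 peaks in the control and 30 with CTCF shRNA, Ror1, a Wnt receptor, 11 and 33, Glis3 25 and 60, Prkg1 34 and 74 and Gas7 16 and 42. In GFP+ cells, Foxp1, a forkhead factor, had 34 and 62 peaks and Grip1 22 and 41, while Tet1, a DNA demethylase of stem cells, had 15 and 9. In Thy1+ cells, Negr1 and Dpyd had 58 and 83 and 33 and 52.

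At day 10, Grik3, a glutamate receptor gene, had 7 peaks in the control, 12 with CTCF overexpression and 0 with Smarca5 shRNA added. Prdm16, a transcription factor of brown fat and blood stem cells, had 12, 15 and 6, and Tspear 4, 8 and 1. In the other direction, Robo1, an axon guidance receptor, had 22, 10 and 14 peaks, Il1rapl1 8, 1 and 3, and Arid5b 25, 16 and 27. Gas7 had 14, 10 and 20 peaks and Hdac9 10, 7 and 15.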
